A study of Arabidopsis thaliana with 8 samples.

How the data were processed

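The samples were cells from Arabidopsis thaliana roots of the Col-0 accession, grown for 5 days, protoplasted, and sorted by fluorescence of a WOX5::GFP reporter, which marks the quiescent center (QC) of the root stem cell niche. There were 4 libraries from wild type plants and 4 from the pan mutant, each labelled a separate biological replicate. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit, cDNA was made and amplified with the SMARTer low input kit, and libraries followed from sheared cDNA. Amplification from few cells adds variation for weakly expressed genes, and neither kit is stated to keep the strand of the RNA. Whether reads of overlapping sense and antisense genes were separated is not stated, so values of such genes are uncertain.

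Per the submitters' processing notes, TopHat2 2.0.13, Cufflinks 2.1.1 and Cuffdiff were used with the TAIR10 genome; their roles, order and settings are not given in the sources used here. The file used is a table of the authors' own comparison in the layout of a Cuffdiff gene-level result. It holds 33201 rows. Expression was deposited by the authors as FPKM (fragments scaled to transcript length in kilobases and to the mapped fragments of the library), with 1 pooled value per genotype and gene; the unit is read from the table's layout. Changes were deposited as log2 of the pan mutant value over the wild type value, with no pseudocount, so a gene listed at 0 in wild type has no finite change. The authors' test statistic is a score with the sign of the change and was not used further. The deposited p-value of each tested gene comes with a q-value adjusted for multiple testing. Recomputing the Benjamini-Hochberg adjustment over the tested genes gave the deposited q-values, with a largest difference of 5.25e-07. The smallest p-value in the table is 5e-05, shared by 853 called genes, so the order of genes at that value is not resolved.

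The table holds no values per library, so no replicate values, standard deviations or standard errors are given here. A linear model of the 8 libraries, gene set tests on it, library correlations, splits of the libraries and the omission of single libraries had been planned before the data were examined and could not be run. The plan's rule for that case was followed: the authors' deposited comparison is described, with genes called at q under 0.05. Depth per library is likewise unknown. Its relative size was read from the lowest values: FPKM times transcript length (the longest transcript in the reference annotation) has its lowest values near the worth of 1 fragment, if effective lengths are close to these lengths, and the 0.1 percentile of the values above 0 was taken as the floor of a genotype.

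Gene names came from the RefSeq annotation of assembly TAIR10.1, matched by locus tag, which found 32218 of the 33201 rows (97.0%). A further 282 rows name more than 1 gene and were kept as they are. Coordinates are those of the table (TAIR10), written 1-based. The lists of genes were fixed before the data were examined: 17 lists with 252 entries, 248 of them distinct genes, of which 16 lists were tested. There was no row of its own for 3 entries (LHW, GSTF8 and UGT73B5). The genes named are PAN and WOX5, the 10 with the largest log2 change in each direction among called genes with at least 5 FPKM in the higher genotype, and, from each list, up to the 4 called members with the largest change or, where none was called, the 2 members with the largest change. The plan also asked that libraries of the 2 genotypes not overlap, which pooled values cannot show. The values of a list member that the rule names are not reported here.

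For each list, the number of called members was set against the number called among tested genes of like expression with an exact stratified hypergeometric test over 20 bins of mean FPKM, one-sided in each direction. Adjusted p-values are Benjamini-Hochberg over 32 tests. This test replaces the planned one, takes the authors' calls as given, and treats genes as independent, which they are not; the correlation between genes could not be estimated. The median log2 change of a list was placed among 10000 random lists matched on expression bin, as a description of these pooled values. Calls were also counted with the deposited p-values adjusted over the list alone. Bootstrap intervals came from 2000 draws of genes within each group, so they measure spread between genes, not between libraries. On simulated data made from the 19590 tested genes with a finite change, 10 of 10 lists of 10 genes lowered by 2 on the log2 scale fell outside the central 95% of random lists, as did 8 of 200 unchanged lists. The exact test called 6 of those 10 lists and 2 of the 200. That simulation drew genes independently and did not use the authors' calls, so its rates need not hold for lists of correlated genes. The floor recovered a simulated depth ratio of 10, with whole fragments, known transcript lengths and the same levels at both depths. It was not tried on fragments shared between genes or on effective lengths. Groups of genes sharing an annotated product or symbol stem, with at least 8 tested members, were tested the same way after the data were seen. Alternatives were another scaling, quantile normalization, pseudocounts, filters on low values and a stricter threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.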

Results

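Gene expression was measured by RNA sequencing in WOX5::GFP-positive cells sorted from the roots of 5-day-old seedlings, in 4 wild type libraries and 4 libraries of the pan mutant. PAN (PERIANTHIA) is a bZIP transcription factor, and WOX5 is a homeobox gene expressed in the QC, the slowly dividing cells around which the root stem cells lie. The comparison asks which genes depend on PAN in cells sorted by the QC marker. The data consist of the authors' deposited table, with 1 pooled FPKM per genotype for each of 33201 rows, so values below carry no error of their own and only the authors' q-value speaks to the spread between replicates. The total number of fragments per library is not known. The floor of FPKM times transcript length in kilobases was 0.0352 in wild type and 0.00349 in pan, a ratio of 10.1. At the 1st percentile the ratio was 7.15, so its size depends on the percentile taken. By this reading the lowest measurable level was several times higher in wild type.

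The targeted gene was nearly lost from the mutant. The authors' deposited table gave PAN (AT1G68640, chromosome 1, 25768539 to 25772543, TAIR10) 19.996 FPKM in wild type and 0.265 FPKM in pan, a log2 change of -6.24 (75.3-fold, q = 0.0386). These coordinates are a locus that the table gives to a neighboring gene, AT1G68630, as well, and the strand of counting is not stated. The sort marker's own gene also fell. WOX5 (AT3G11260, chromosome 3, 3527575 to 3528433) stood at 205 FPKM in wild type and 8.27 FPKM in pan in the authors' deposited table, a log2 change of -4.63 (24.8-fold, q = 0.00116).

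Loss of PAN went with broad change in the sorted cells. Of 19789 genes tested in the authors' deposited table, 3531 (17.8%) were called, 1586 higher and 1945 lower in pan. Among calls with a finite change the median log2 change was 1.602 for the higher genes and -2.16 for the lower genes. The median over all tested genes with a finite change was -0.17, and it moved with expression level, so list medians below are set against random lists matched on expression. The medians of those random lists ran from -0.66 for the photosynthesis list to 0.13 for the salicylate list. The direction of calls with a finite change moved with expression level. Of those averaging 1 to 5 FPKM 9.2% were higher, and of those at 100 FPKM or more 79.3% were higher. These shares leave out 154 genes called higher and listed at 0 in wild type, and 4 called lower and listed at 0 in pan. The 150 of the 154 with a transcript length had a median of 1.47 FPKM in pan, so the low classes are the most affected. A further 13403 rows were not tested, and 9 rows with too many fragments, ACT2 among them, are listed at 0 in pan without an estimate.

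**Figure D1:**
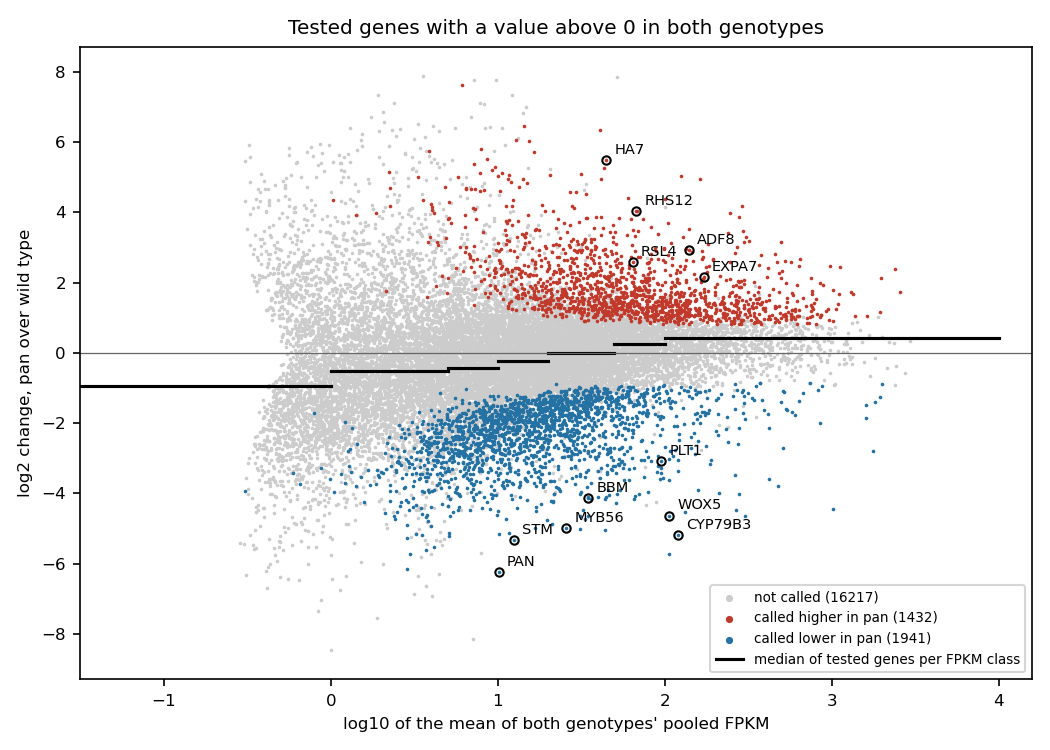
Log2 change (pan over wild type) of the 19590 tested genes with a value above 0 in both genotypes, against log10 of the mean of the pooled FPKM of wild type and pan; each point is a gene, colored by the authors' call, and black lines are medians per FPKM class. PAN and WOX5 lie at -6.24 and -4.63, and the class median runs from -0.94 under 1 FPKM to 0.43 at 100 FPKM or more.

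The falls are ranked among called genes with a finite change and at least 5 FPKM in the higher genotype. After PAN, the authors' deposited table listed the lowest of these log2 changes for the histone deacetylase HDA18 (-6.15), SKS2 (-5.73), the major facilitator superfamily gene AT1G59740 (-5.72), ACI1 (-5.62) and the F-box gene AT3G58950 (-5.52). STM, the homeobox gene known for maintaining the shoot meristem, fell from 24.3 to 0.601 FPKM (log2 -5.34, q = 0.00340) in the authors' deposited table. The amino acid permease AAP2 (-5.26), IPMI1 (-5.22) and CYP79B3 (-5.18), which makes indole-3-acetaldoxime from tryptophan, completed the 10 lowest log2 changes of such called genes in the authors' deposited table. Of these 10, AT1G59740 and CYP79B3 were the most abundant in wild type, at 207 and 234 FPKM in the authors' deposited table. This order holds without a pseudocount and rests on levels near 0 in pan, such as 0.0796 FPKM for HDA18 in the authors' deposited table. With a pseudocount of 1, HDA18 (-2.62) and SKS2 (-2.63) lay above AT1G59740 (-5.40) and CYP79B3 (-4.98).

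The rises are ranked among called genes with a finite change and at least 5 FPKM in pan. The authors' deposited table listed the largest of these log2 changes for the NB-ARC and LRR gene AT5G05400 (7.61), the E1-E2 type ATPase gene AT3G63380 (6.47), the extensin family gene AT2G47530 (6.33) and ROPGEF10 (6.06), an activator of ROP GTPases. The GPI-anchored protein gene AT5G01280 (6.03), the rhamnogalacturonate lyase gene AT4G37950 (5.73) and the protein kinase genes AT5G61350 (5.71) and AT5G18910 (5.52) followed in the authors' deposited table. HA7, a plasma membrane proton pump, rose from 1.94 to 87.1 FPKM (log2 5.49) in the authors' deposited table. The extensin-like gene AT4G08410 (log2 5.80 in the authors' deposited table) has a close relative in AT4G08400, which can share reads with it, so its value is uncertain. The order of the rises also holds without a pseudocount, and AT5G05400 stood at 0.0620 FPKM in wild type in the authors' deposited table. With a pseudocount of 1, AT2G47530 (5.35) and HA7 (4.91) lay above AT3G63380 (4.48) and AT5G05400 (3.63). Another 154 genes called higher are listed at 0 in wild type and have no fold; the highest in pan, AT4G23271, stood at 49.2 FPKM in the authors' deposited table and is a very short gene.

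Regulators of the stem cell niche fell together. Of 27 tested members, 18 fell and none rose: PLT1, PLT2, PLT3, BBM, SHR, SCR, MGP, MYB56, AGL42, RBR1, HAN, WIP2, WIP4, WIP5, ACR4, RGF1, RGF2 and RGF3. The list holds the PLETHORA and BABY BOOM factors that maintain root stem cells, the SHR and SCR pathway of the ground tissue and QC, and RGF peptides that promote PLETHORA activity. In the authors' deposited table, MYB56 fell from 49.8 to 1.56 FPKM (31.9-fold), BBM from 65.8 to 3.73 FPKM (17.7-fold), WIP5 from 66.9 to 5.08 FPKM (13.2-fold) and HAN from 12.8 to 0.978 FPKM (13.04-fold). The median log2 change was -2.54, below every one of 10000 random lists (-1.57 with a pseudocount of 5), and 18 falls compared with 2.86 expected (exact stratified hypergeometric test, adjusted p = 2.19e-11). Adjusted over the list alone, 19 members were lower. WOX5 itself was lower in the same cells, as given above.

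Markers of the root cap fell as well. Of 11 tested columella and lateral root cap genes, 6 fell (SMB, BRN1, BRN2, FEZ, PIN3 and CEL5) and none rose. BRN1 and BRN2 are NAC factors of root cap maturation, with SMB; FEZ is a NAC factor of root cap stem cells. The authors' deposited table gave PIN3 a change from 69.4 to 11.0 FPKM, FEZ from 24.6 to 6.43 FPKM, BRN1 from 148 to 40.2 FPKM and SMB from 45.9 to 12.95 FPKM. The list's median was -1.72, with 1.32 falls expected (exact stratified hypergeometric test, adjusted p = 0.00604; 6 lower when adjusted over the list alone). Beside this stood the epidermal and root hair markers, whose median exceeded that of the root cap list by 3.28 (95% bootstrap interval 1.705 to 3.9995) and whose count of calls did not pass, and the fall of WOX5.

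The medians of epidermal and stele markers lay on opposite sides of 0. Among 14 tested epidermis and root hair genes, 5 rose and none fell. ADF8 rose from 32.6 to 246 FPKM (7.55-fold), RSL4, a basic helix-loop-helix factor of root hair growth, from 18.5 to 110 FPKM (5.95-fold), MYB23 from 11.1 to 50.9 FPKM and the expansin EXPA7 from 63.0 to 279 FPKM in the authors' deposited table. The fifth was EXPA18. The median, 1.56, lay above all random lists, and 9 members were higher when adjusted over the list alone, while the count of calls did not pass (2.03 expected; exact stratified hypergeometric test, p = 0.0350, adjusted p = 0.187). Of 14 tested stele and vascular genes, 4 fell, CVP2, ATHB8 and PHB among them, and WOL, a cytokinin receptor, rose. The authors' deposited table gave CVP2 5.55 and 0.187 FPKM, ATHB8 29.8 and 3.01 FPKM, PHB 7.41 and 0.890 FPKM, and WOL 28.1 and 70.8 FPKM in wild type and pan. The stele median was -1.62 (percentile 1.2 of random lists; 0.748 falls expected; exact stratified hypergeometric test, adjusted p = 0.0239; 1 higher and 4 lower when adjusted over the list alone). With a pseudocount of 5 the stele median was -0.30, inside the central 95% of random lists, and it was -3.31 over the 3 members with a mean of at least 5 FPKM. It was -0.81 with a pseudocount of 1 and -0.99 with centring per expression bin, which subtracts the median of each bin and was chosen after the data were seen.

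Of 12 tested endodermis and cortex genes, CASP1, which builds the Casparian strip, rose from 48.4 to 145 FPKM and AT4G28100 fell from 57.0 to 4.99 FPKM in the authors' deposited table. The median was 0.95 (percentile 99.5), and the exact stratified hypergeometric test gave an adjusted p of 1 in each direction, with 1 higher and 1 lower adjusted over the list alone. None of 11 tested photosynthesis genes of green tissue was called, over all genes or adjusted over the list alone. Among tested members the largest changes, of LHCB1.2 (1.35 and 0.201 FPKM) and LHCA1 (1.25 and 0.284 FPKM), were not called in the authors' deposited table.

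**Figure D2:**
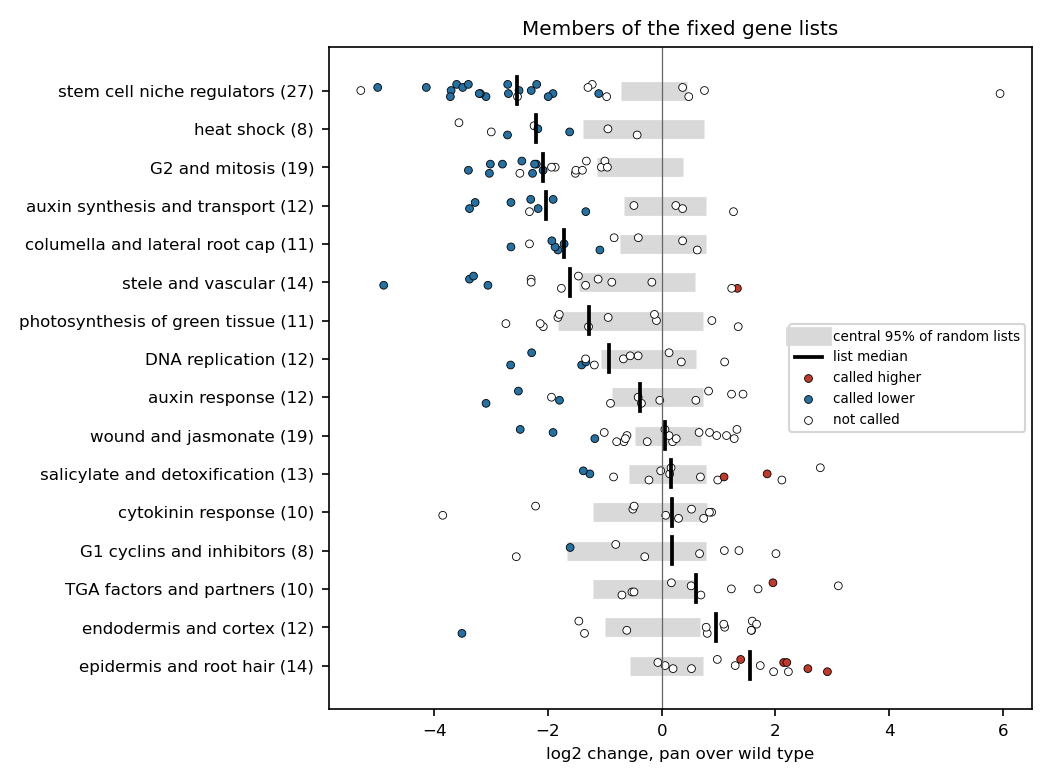
Log2 change (pan over wild type) of the tested members with a finite change in each of the 16 fixed lists, with their number in parentheses; each point is a gene colored by the authors' call, black bars are list medians and gray bands the central 95% of 10000 random lists matched on expression. The niche regulators' median is -2.54 and the epidermis and root hair median 1.56, both outside their bands.

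Genes of G2 and mitosis fell in pan. Of 19 tested, 9 fell and none rose, and all 19 had a negative log2 change. In the authors' deposited table, the mitotic cyclin CYCB2;3 fell from 27.6 to 2.61 FPKM, the Aurora kinase AUR1 from 31.4 to 3.84 FPKM, CYCA1;1 from 20.4 to 2.53 FPKM and CYCB1;4 from 20.4 to 2.93 FPKM. The median was -2.09 (-1.05 with a pseudocount of 5), below all random lists (2.45 falls expected; exact stratified hypergeometric test, adjusted p = 0.00252; 15 lower when adjusted over the list alone). These falls stood beside a median of 1.56 in the epidermal and root hair markers, whose count of calls did not pass, and the fall of WOX5 in the same cells. Of 12 tested DNA replication genes, ETG1, MCM6, MCM2 and MCM3 fell, and the list did not pass (median -0.93, percentile 4.59; 1.63 falls expected; exact stratified hypergeometric test, adjusted p = 0.273; 4 lower when adjusted over the list alone). Its median was -1.18 at a mean of at least 5 FPKM, outside the central 95% of random lists, and -0.59 with centring per expression bin. The authors' deposited table gave ETG1 43.0 and 6.82 FPKM, MCM6 21.7 and 4.44 FPKM, MCM2 30.7 and 11.6 FPKM and MCM3 23.1 and 9.15 FPKM in wild type and pan. Of 8 tested G1 cyclins and inhibitors, CYCD3;3 alone was called, over all genes and adjusted over the list alone, falling from 26.3 to 8.60 FPKM in the authors' deposited table. The G1 list had a median of 0.18 and a mean of -0.02, which differ in sign, and did not pass (exact stratified hypergeometric test, adjusted p of 1). That median was 0.67 at a mean of at least 5 FPKM, 0.35 with median-of-ratios scaling, 0.12 with a pseudocount of 5 and 0.83 with centring per expression bin.

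Auxin synthesis and transport genes fell, beside the same medians of epidermal (1.56) and niche (-2.54) markers. Of 12 tested genes that make or carry auxin, 7 fell and none rose, with YUC7, PIN3, PIN4, YUC3, YUC8 and TAA1 among those that fell. YUC7, a flavin monooxygenase of auxin synthesis, fell from 8.67 to 0.891 FPKM and the efflux carrier PIN4 from 201 to 40.8 FPKM in the authors' deposited table; PIN3 is given above and belongs to another list as well. The median was -2.04 (-1.27 with a pseudocount of 5), below all random lists (1.34 falls expected; exact stratified hypergeometric test, adjusted p = 0.00152; 1 higher and 8 lower when adjusted over the list alone). Of 12 tested auxin response genes, IAA20 fell from 148 to 17.3 FPKM, GH3.5 from 48.6 to 8.46 FPKM and IAA30 from 73.9 to 21.2 FPKM in the authors' deposited table, and the list did not pass (median -0.39; exact stratified hypergeometric test, adjusted p = 0.372; 5 lower when adjusted over the list alone). Its median was -0.66 (percentile 4.55) at a mean of at least 5 FPKM, -0.22 with median-of-ratios scaling and -0.19 with centring per expression bin. Of 11 tested cytokinin response genes, ARR17 was called, over all genes and adjusted over the list alone, listed at 0 in wild type and 1.29 FPKM in pan in the authors' deposited table. The cytokinin list's median (0.18) and mean (-0.37) differ in sign, with an adjusted p of 1 in each direction (exact stratified hypergeometric test). Median-of-ratios scaling gave a cytokinin median of 0.35, pseudocounts of 0.1 and 1 gave 0.29, and centring per expression bin gave 0.09.

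PAN belongs to the TGA class of bZIP factors. Of 10 tested TGA factors and partners, NPR1, the salicylate receptor and cofactor, rose from 4.85 to 18.9 FPKM in the authors' deposited table, and no other member was called, over all genes or adjusted over the list alone (median 0.60, percentile 97.1; exact stratified hypergeometric test, adjusted p of 1). Among 13 tested salicylate and detoxification genes, OPR2 and OPR1, which encode oxophytodienoate reductases, rose and the glutathione transferases GSTU2 and GSTU1 fell. The authors' deposited table gave OPR2 60.8 and 220 FPKM, OPR1 365 and 781 FPKM, GSTU2 53.6 and 20.6 FPKM and GSTU1 105 and 43.8 FPKM in wild type and pan. That list did not pass in either direction (median 0.16; exact stratified hypergeometric test, adjusted p of 1; 3 higher and 3 lower when adjusted over the list alone). The salicylate median was 0.42 at a mean of at least 5 FPKM, 0.33 with median-of-ratios scaling and 0.56 with centring per expression bin.

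No tested wound, jasmonate or heat shock gene, which protoplasting can induce, was called higher in pan. Of 19 tested wound and jasmonate genes, JAZ5 fell from 20.3 to 3.62 FPKM, SZF1 from 34.97 to 9.30 FPKM and ZAT10 from 81.4 to 36.0 FPKM in the authors' deposited table. The wound list's median (0.06) and mean (-0.14) differ in sign and it did not pass (exact stratified hypergeometric test, adjusted p = 0.951; 3 lower when adjusted over the list alone). Median-of-ratios scaling gave a wound median of 0.22, and centring per expression bin turned it to -0.24. Of 8 tested heat shock genes, HSP70 fell from 107 to 16.3 FPKM, the factor HSFA2 from 11.8 to 2.60 FPKM and the chaperone HSP101 from 16.7 to 5.44 FPKM in the authors' deposited table. All 8 had a negative log2 change, with a median of -2.21 (percentile 0.05; -1.10 with a pseudocount of 5) and 6 lower when adjusted over the list alone, while the count of calls did not pass (exact stratified hypergeometric test, adjusted p = 0.273). No result here has a check in single libraries, and list tests treat genes as independent. At a mean of at least 20 FPKM the called genes were 59.5% higher in pan, against 44.9% over all tested genes, a filter chosen after the data were seen.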

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

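The tests in this part were chosen after the values were seen. Among the rows that the authors left without a test, 5828 are listed at 0 in wild type and above 0 in pan, against 180 with the reverse; this signal lies outside the comparisons of the report and stood out because of that imbalance. The levels are low: the median in pan is 0.0399 FPKM over the 5707 of these rows with a transcript length, and 179 of all such rows reach 1 FPKM. A shallower set of wild type libraries is a candidate explanation. At the pan level, 70.9% of the 5707 would be expected to give fewer than 3 fragments over the wild type libraries, taking the largest depth that the wild type floor allows. Being left without a test itself selects for few fragments, so this decides nothing and the explanation stays open. For the called genes listed at 0 in wild type it stays open too: at the smallest depth the floor allows, 0% of the 150 with a transcript length would be expected to give fewer than 3, but a call against 0 itself needs such a pan level.

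The niche and root cap lists held more falls than genes of like expression, while 5 of 14 epidermal and root hair genes were called higher, a count that did not pass (adjusted p = 0.187, exact stratified hypergeometric test). A smaller share of QC cells among the sorted cells, with all other root tissues rising alike, is argued against: the median log2 change of the epidermal markers exceeded that of the stele markers by 3.18 (95% bootstrap interval 1.98 to 4.53), and by 1.60 (0.66 to 2.21) with a pseudocount of 5; 3 of the 14 stele markers reach a mean of 5 FPKM. More root hair cells among the sorted cells may account for part of the pattern: of 14 genes that the annotation names root hair specific, none of them in the fixed lists, 11 were called higher, against 1.72 expected (exact stratified hypergeometric test, p = 2.23e-09). That test used genes already seen to be higher, so it cannot establish the explanation. Nor was a higher median particular to root hair genes. The epidermal list also holds factors of non-hair cells. Among them, MYB23 was called higher, while GL2 (log2 1.97) and WER (0.20) were not called in the authors' deposited table. The endodermis and cortex median exceeded the stele median by 2.56 (95% bootstrap interval 0.61 to 3.99), with 1 gene called higher and 1 lower. The intervals in this paragraph resample genes, not libraries, so what they argue holds for these pooled values only. An effect of PAN within the sorted cells, with the niche regulators' median at -2.54, cannot be told apart from a change in which cells were sorted, because the table has 1 pooled level per genotype and the reporter's own gene fell.

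Over tested genes with a finite change, the log2 change rose with expression level. Its median was -0.94 under 1 FPKM and 0.43 at 100 FPKM or more. A single scaling factor per genotype shifts every class alike and so makes no such trend, whatever the data. A shallower set of wild type libraries would end the trend once both genotypes are far above their floors, and it did not end there: the median at 100 FPKM or more exceeded that at 20 to 50 FPKM by 0.42 (95% bootstrap interval 0.37 to 0.49). This interval resamples genes, not libraries, so variation between libraries is not in it and the argument holds for these pooled values only. The argument also covers only the rise above 20 FPKM. From under 1 FPKM to the class of 20 to 50 FPKM the median rose from -0.94 to 0.005, and a contribution of depth to that rise stays open. Differences in cDNA amplification and a biological change of abundant genes stay open and were not tested.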

How the results depend on the processing

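The alternatives were planned before the data were examined, except centring per expression bin, the filters at 1 and 20 FPKM, the threshold of q under 0.01 and the omission of calls listed at 0, which were chosen after seeing the data. Scaling cannot alter the authors' calls, so it bears on the sizes of change. Of the counts of called genes under the alternatives, 32 stayed within 1.5 times the main count and 6 did not. The 32 include counts of all called genes under scaling and quantile normalization, where the calls cannot change. With q under 0.01, 841 genes were higher and 868 lower, all of them changed at least 2-fold. With a mean of at least 20 FPKM, 927 were lower, 863 of them at least 2-fold; fewer genes are tested under that filter. The main counts were 1586 and 1945, and 1475 and 1922 at least 2-fold. Of the list medians, 98 kept their direction and their side of the central 95% of random lists. These include the medians under median-of-ratios scaling, which shifts list and random lists alike and cannot move a list across that range's edge. The wound and jasmonate median, inside that range, turned from 0.06 to -0.24 with centring per expression bin. The stele median moved inside with a pseudocount of 5 (-0.30), the TGA median moved outside with a pseudocount of 5 (0.45), and the DNA replication median moved outside at a mean of at least 5 FPKM (-1.18); the cause was not tested. With a pseudocount of 5, 8 of 17 list medians changed in size by over 1.5 times. The 126 values of named genes kept their sign. A pseudocount added to both genotypes cannot change a sign, and the scaling shift of -0.17 was small beside these changes, so this says little. With pseudocounts of 1 and 5 the size moved by over 1.5 times for 10 and 17 of 21 genes. With a pseudocount of 5, PAN was at -2.25, HDA18 at -1.07 and AT5G05400 at 1.76. No paired analysis was possible because the table holds no values per library. For the same reason the other tests and weights of the linear model, the estimated correlation, fry, library correlations and leaving out each library were not run; nor was an analysis with no filter, since untested genes carry no test. The higher floor of the wild type values limits what can be said of genes listed at 0 there.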

Other observations

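The lists and tests in this part were chosen after the data were seen. Genes of glucosinolate synthesis were lower in pan: of 15 tested, 11 fell and none rose, with a median log2 change of -3.63, below all random lists (1.44 falls expected; exact stratified hypergeometric test, p = 1.03e-09, not adjusted, on a list drawn up after CYP79B3 and IPMI1 were seen among the lowest genes). In the authors' deposited table, CYP79B2 fell from 579 to 23.0 FPKM, CYP83B1 from 299 to 19.9 FPKM, SOT17 from 40.9 to 1.41 FPKM and MYB34, a regulator of the indole branch, from 113 to 9.15 FPKM. GGP1 was not called, at 405 and 578 FPKM in the authors' deposited table. These falls stood beside a median of 1.56 in the epidermal and root hair markers, whose count of calls did not pass, and of -2.54 in the niche regulators, and beside the fall of WOX5 (log2 -4.63 in the authors' deposited table). Among 10 genes of shoot meristem and boundary, 5 were tested; KNAT6 fell, from 11.0 to 1.87 FPKM in the authors' deposited table, as did STM, whose fall prompted this list. KNAT1 (log2 0.31), KNAT2 (-1.90) and CLV1 (1.26) were not called in the authors' deposited table, and the list's median of -1.90 lay inside the central 95% of random lists (percentile 4.27). The 2 falls, STM itself among them, compared with 0.327 expected (exact stratified hypergeometric test, p = 0.0297, not adjusted). WUS and CUC1 were not tested and are listed at 0 in wild type in the authors' deposited table. Transcripts of the plastid genome summed to 8875 FPKM in wild type and 2225 FPKM in pan in the authors' deposited table, with 28 of 77 tested genes lower, none higher and a median log2 change of -2.05. Leaving out ATMG00020, which had too many fragments, those of the mitochondrial genome summed to 1969 and 1406 FPKM in the authors' deposited table. ATMG00020 stood at 7703 FPKM in wild type in the authors' deposited table and has no estimate in pan. Of 51 tested mitochondrial genes, 1 was higher and 2 were lower, with a median of -0.59. The organelle values stood beside the same epidermal and niche medians and the fall of WOX5.

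Of 545 groups of genes sharing an annotated product or symbol stem, tested in both directions, 7 held more higher calls than genes of like expression and 1 more lower calls, after Benjamini-Hochberg adjustment over 1090 tests. The group named for a cysteine and histidine rich C1 domain had 23 of 105 genes higher and 4 lower (4.07 rises expected; exact stratified hypergeometric test, adjusted p = 4.23e-09). The largest changes among its called genes were falls, of AT5G40320 (log2 -4.18) and AT1G35610 (log2 -3.97) in the authors' deposited table. Proline-rich extensins, structural proteins of the cell wall, had 8 of 11 higher (adjusted p = 0.00572, exact stratified hypergeometric test), and EXT13 rose from 176 to 1123 FPKM in the authors' deposited table. Root hair specific genes had 11 of 14 higher, and RHS19 rose from 56.9 to 554 FPKM and RHS12 from 7.79 to 128 FPKM in the authors' deposited table. The symbol stem RHS, with 7 of 9 higher, shares genes with this group, so the 7 groups are not all distinct. The major facilitator superfamily group had 17 of 83 higher and 6 lower, with a median log2 change of 0.43. Those rises compared with 5.82 expected (exact stratified hypergeometric test, adjusted p = 0.00572). Aquaporins, the water channels of plasma membrane and vacuole, were counted by product because the symbol stems PIP and TIP also take in other genes: 15 of 28 tested were higher and 1, TIP3;1, lower (5.46 rises expected; exact stratified hypergeometric test, p = 1.51e-05, not adjusted). TIP2;3 rose from 28.9 to 460 FPKM and PIP1;5 from 89.9 to 378 FPKM in the authors' deposited table. The stem RGF was the group with more lower calls, 5 of 8 (0.780 expected; exact stratified hypergeometric test, adjusted p = 0.0360), of which RGF8 fell from 508 to 22.9 FPKM in the authors' deposited table; RGF1, RGF2 and RGF3 are also niche regulators of the report.

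A hypothesis tested with a negative result was that a chromosome segment linked to PAN differs between the lines, which would raise the share of called genes nearby. Within 1 Mb of PAN, 59 of 347 tested genes were called, 17.0% (95% exact binomial interval 13.2 to 21.4), against 17.9% elsewhere (exact Fisher test, p = 0.724). Only a large excess of calls is argued against, because that interval leaves room for a segment that changes few of these genes.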
